A study of Mus musculus with 4 samples.

How the data were processed

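Gene expression was measured in small intestinal crypts of 2 mice and in organoids cultured from them for 1 week. Per the labels' protocols, tissue was incubated in 2 mM EDTA, the crypt fraction was passed through a 70 µm strainer, and 500 crypts were plated in 50 µl of Matrigel. The medium contained 10 to 50 ng/ml EGF, 500 ng/ml R-spondin and 100 ng/ml Noggin. The labels name Trizol for RNA isolation and the series' design text names an RNeasy kit, so the kit used is not settled. Per the labels' protocols, 500 ng of total RNA was amplified and labelled with Cy3 or Cy5. Crypt and organoid RNA of a mouse shared each array, and each mouse had 2 arrays of opposite dye orientation. Both arrays of a mouse are technical repeats of the same 2 RNAs and count as 1 replicate, so n = 2 mice.

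Each deposited scanner file holds 45018 spots, of which 1639 are controls, for 41174 probes. Per the file headers the images were read with Agilent Feature Extraction 10.2.1.3, whereas the submitters' processing notes name version 9.5.3. The deposited intensity values are mean spot signals and median local backgrounds in each dye on a linear scale. The deposited log10 ratio of Cy5 over Cy3 is the scanner software's own, background-subtracted and dye-normalized per the file headers, and it equalled the log10 of the processed signals within 0.001 for 76.9% of non-control spots. The authors' series matrix holds 1 value per probe and array. Set against the scanner ratios, the deposited matrix values were log2 ratios of Cy5 over Cy3 on all 4 arrays (r from 0.978 to 0.992). Each column's median was 0, and 6734 to 8950 values per array were exactly 0. How the authors centred the matrix is not given in the sources used here. The median signal was 161 to 178 in Cy3 and 266 to 312 in Cy5. Saturated spots numbered 0 to 1 per array, and 161 to 197 non-control spots per array carried an outlier mark. Agilent's spike-in controls had the same sign of Cy5 over Cy3 on all 4 arrays.

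The arrays were analysed with limma 3.58.1 in R 4.3.3. Background was corrected with normexp (offset 50) and each array was normalized by loess, with control spots at weight 0. Spots with an outlier mark in either dye were left out, and spots of a probe were averaged. Ratios were turned to organoid over crypt by the dye labels. The turned ratios of a mouse's 2 arrays correlated across genes with r = 0.837 in mouse 1 and r = 0.850 in mouse 2. A probe was tested if it was unmarked on all 4 arrays and well above background in all 4 crypt or all 4 organoid channels, which left 21923 probes. Probes were named by accession through NCBI RefSeq's gene table for GRCm38.p6 where they matched (24844 of 41174), and by the file's own gene name otherwise. Positions are those of the probes in mm9, per the files. A gene with several tested probes was represented by the probe of highest mean intensity, which left 15538 genes. Of 700 other tested probes of the genes that passed the test, 38 (5.43%) had the opposite sign. Of the genes tested, 14374 were well above background in all 8 channels. Where a gene was not well above background in any channel of 1 tissue, a lower bound of the fold is given. It sets the brighter tissue's mean against the dim tissue's, in which each array's value is at least the lowest signal of any probe well above background.

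The 2 arrays of a mouse were averaged, and the 2 mouse means were tested against 0 with lmFit and eBayes (two-sided). With 2 mice each gene has 1 residual degree of freedom, and eBayes added 4.16 prior degrees of freedom with a prior SD of 0.201. Genes with a Benjamini-Hochberg adjusted p under 0.05 are said to have passed the test. Dye bias cancels in a mouse's mean. Its SD across genes was 0.15 on the log2 scale, against 0.52 for organoid over crypt. Channel correlations were computed after loess and quantile normalization of average intensities between arrays (Aquantile).

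Before the data were examined, 34 lists of genes were fixed, for the lineages, signalling pathways and metabolism of the epithelium and for other cell types of the gut. Lists were tested with limma's camera on the mouse means (preset correlation 0.01, two-sided) with Benjamini-Hochberg adjustment over the 34 lists. Camera called 20 lists, 8 higher and 12 lower. With a correlation estimated from the 4 arrays (dye as a covariate, 2 residual degrees of freedom) no list passed. The smallest adjusted p was 0.302, and 4 lists had an unadjusted p under 0.05 by it. A test with 2 degrees of freedom has little power. The enterocyte list, whose estimated correlation was -0.03, had an unadjusted p of 0.00888 by it. Not passing it therefore does not show that correlation between genes accounts for a shift. Estimated correlations reached 0.85 (glycolysis and hypoxia), so for such lists correlation cannot be set aside. Limma's fry, which tests whether a list's genes move one way on balance, called none, its smallest adjusted p was 0.0662, and 16 lists had an unadjusted p under 0.05. The named genes were fixed by rule beforehand. They are the 10 highest and 10 lowest genes past the test with 1 direction on all 4 arrays, passing over clone, predicted-gene and transcript identifiers. From each list come up to 3 members past the test with the largest change, or the 2 brightest members if none passed. To these were added Lgr5, Ascl2, Olfm4, Lyz1, Muc2, Chga, Vil1 and Mki67. Where 5 or fewer members of a list passed in a direction, those outside the rule are named too, chosen after their values were seen (Slc12a2, Myc, Fas, Duoxa2, Ccl20, Cyp1a1, Srxn1, Ftl1, Mt4, Slc39a4, Fth1, Tfrc, Sesn2, Creld2, Hsp90b1, Ier3 and Jun). Gsta1, Gsta2 and Gsta4 were named in the same way. Of the genes taken by the rule, 3 are not reported here.

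The pairing of RNAs was checked with sex-linked genes. Xist was well above background in crypt and organoid of mouse 1 on both arrays and in neither RNA of mouse 2. Ddx3y, Eif2s3y and Kdm5d showed the reverse for their brightest probes, so both RNAs of a mouse matched. All 4 arrays lay on 1 slide scanned once, so slide and scan could not be tested as batches. The whole procedure was tested on simulated data, with 10 simulations of the organoid against crypt comparison in 15538 genes from the fitted noise and dye effects, each with 200 changed genes. It recovered 1.19% of genes changed 1.5-fold, 27.9% of those changed 2-fold and 95.8% of those changed 4-fold, none in the wrong direction. On average 7.70% of its calls were unchanged genes, above the nominal 5%. The real comparison gave 1697 calls. Because the adjustment is stricter where fewer genes change, the simulated shares need not hold for the real comparison. Simulated over the same genes with no list shifted, camera called 0 of 34 lists, but those genes were simulated without correlation. Alternatives covered the background correction, the normalization, the source of values, the filters, the choice of probes, the treatment of the dye swap, the variance model, each dye orientation alone, each mouse alone and the set test.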

Results

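RNA from freshly isolated mouse small intestinal crypts was compared with RNA from organoids grown for 1 week from another part of the same crypts. Crypts are the epithelial pits that hold the intestinal stem cells, and organoids are the closed epithelial structures that grow from them in a gel with EGF, R-spondin and Noggin. The crypts came from 2 mice. For each mouse, crypt and organoid RNA were labelled with different dyes and hybridised together on an Agilent whole mouse genome array, and again with the dyes swapped, which gave 4 arrays. Each array therefore gives the ratio of organoid to crypt RNA within a mouse, and the 2 arrays of a mouse were averaged, so that n = 2 mice throughout. Values are log2 ratios of organoid over crypt with the SD of the 2 mice. Between 53.8% and 67.3% of probes were well above background in the crypt channel, and between 51.5% and 61.7% in the organoid channel. The number of arrays and of mice limits the precision of every value.

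The first question was which genes differed between organoids and the crypts they came from. Of 15538 genes tested, 1697 (10.9%) passed the test, 844 higher and 853 lower in organoids. The highest was Cbr3, a carbonyl reductase, at 5.23 ± 0.18 (adjusted p = 0.00121, 37.5-fold). Gsta3, a glutathione transferase, rose by 4.80 ± 0.41, and Scd2, a fatty acid desaturase, by 4.76 ± 0.22. The metal-binding protein gene Mt2 rose by 3.92 ± 0.10 and the hypoxia-inducible gene Bnip3 by 3.43 ± 0.09. The water channel gene Aqp8 (3.29 ± 0.11), Ankrd37 (3.29 ± 0.78), the oxygen-sensing hydroxylase gene Egln3 (3.12 ± 0.48) and the duodenal iron reductase gene Cybrd1 (3.08 ± 0.31) were also among the 10 highest. The lowest was Lct, which encodes lactase, at -4.47 ± 0.06 (adjusted p = 0.00121, 22.2-fold lower in organoids). The antimicrobial lectin gene Reg3b had -4.36 ± 0.15, the vitamin B12 receptor gene Cubn -4.19 ± 0.17, and the scaffold gene Pdzk1 -3.92 ± 0.10. Bst1 (-3.88 ± 0.12), Slc5a4a (-3.87 ± 0.15), Aspa (-3.65 ± 0.31), Apol10a (-3.64 ± 0.35), Rtp4 (-3.57 ± 0.20) and the chemokine gene Ccl5 (-3.51 ± 0.14) were the others of the 10 lowest. Cubn was well above background on 3 of the 4 organoid channels. Cybrd1 was at 1.86 with the mean over probes. The adjusted p of the 10 highest and 10 lowest genes ranged from 0.00121 to 0.00456.

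**Figure D1:**
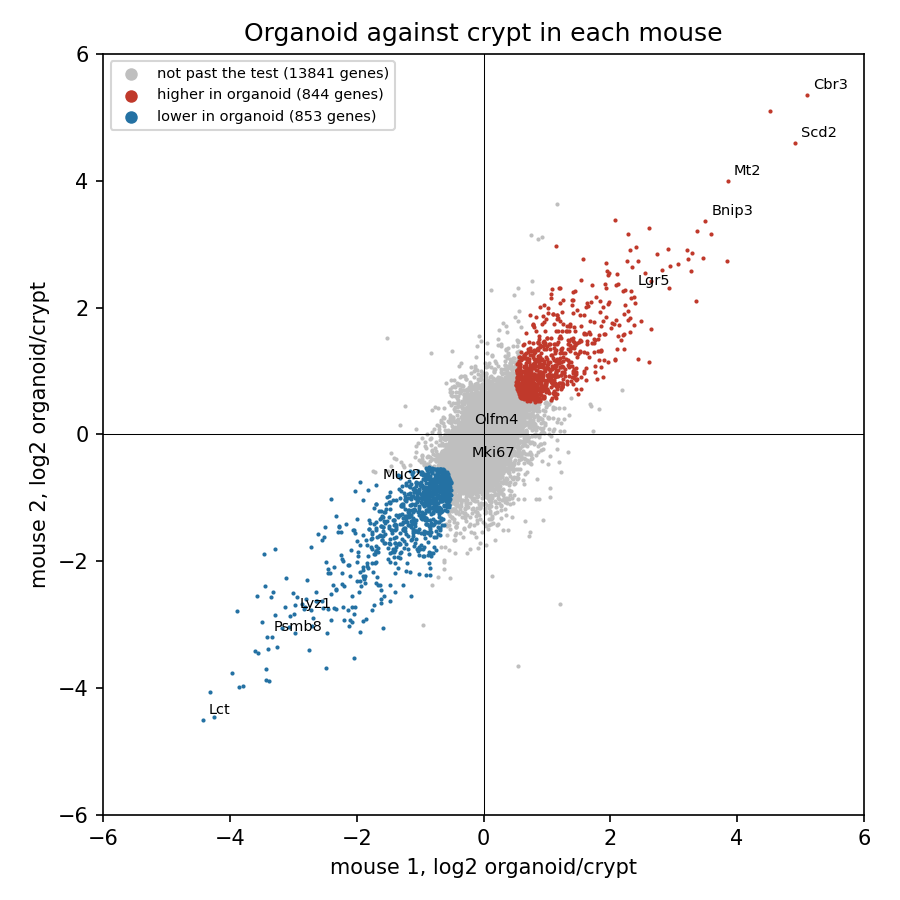
Log2 ratio of organoid over crypt in mouse 1 (x axis) and mouse 2 (y axis), 1 point per gene tested. Red points (844) and blue points (853) passed the test, which favours genes whose mice agree, so they lie along the diagonal. Olfm4 and Mki67 lie near 0.

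The test was limma's moderated test of the 2 per-mouse ratios against 0, with Benjamini-Hochberg adjustment. An unadjusted p under 0.05 was reached by 4294 genes, and 1695 of the 1697 had the same direction on all 4 arrays. The test itself favours genes whose mice agree. Over all genes tested, 68.9% had the same direction in both mice. The count was 224 when arrays were only centred on their medians (130 higher, 94 lower), 677 without the dim-probe filter, 908 with the organoid in Cy3 alone, 3709 with 4 arrays and a dye effect, and 3080 with the mouse as a random block. Without a test, 251 genes were at least 2-fold higher and 358 at least 2-fold lower in both mice, together 3.92% of the genes tested. These became 513 and 617 with the scanner's own ratios, 497 and 633 with the deposited matrix, 364 and 194 with median centring, 379 and 426 in mouse 1 alone, and 484 and 733 in mouse 2 alone. In contrast, 14127 genes (90.9%) lay within 2-fold in both mice.

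The second question was how close organoids were to crypts over all genes. Across the 15538 genes, crypt and organoid intensities of the same mouse correlated with r = 0.971 in mouse 1 and r = 0.959 in mouse 2. The crypts of the 2 mice correlated with r = 0.992, and their organoids with r = 0.989. The median absolute difference was 0.18 and 0.28 on the log2 scale between crypt and organoid of mouse 1 and mouse 2. It was 0.13 between the crypts and 0.17 between the organoids of the 2 mice. The correlations are across genes, which are not independent replicates, and no test was made of them. Crypt and organoid RNA of a mouse shared arrays, whereas the 2 mice were on different arrays, so the pairs compared differ in this too. The organoid over crypt ratios of the 2 mice correlated across genes with r = 0.767 (Spearman's rho 0.602).

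Lgr5, the receptor gene that marks crypt base stem cells, rose 4.89-fold in organoids (log2 2.29 ± 0.05, adjusted p = 0.00202; probe at chromosome 10, 114888847 to 114888906 in mm9). A second Lgr5 probe was not well above background in any of the 4 crypt or 4 organoid channels. Of 15 stem cell genes tested, 4 rose, none fell and 11 did not pass the test, with a list median of 0.43 (mice 1 and 2: 0.43 and 0.42). Smoc2 rose by 0.95 ± 0.17, the receptor tyrosine kinase gene Ephb3 by 0.92 ± 0.01 and the chloride cotransporter gene Slc12a2 by 0.70 ± 0.03. Olfm4, another crypt base marker, was at -0.09 ± 0.21 (adjusted p = 0.763; chromosome 14, 80421398 to 80421457), and the stem cell transcription factor gene Ascl2 at -0.22 ± 0.12 (adjusted p = 0.363; chromosome 7, 150154439 to 150154498). Adjusted over the list alone, 9 members rose and 1 fell. Among 17 Wnt target genes, Lgr5, Ephb3 and Myc (0.78 ± 0.00) rose, and the metalloproteinase gene Mmp7, which Paneth cells also express, had -1.65 ± 0.21 and was the 1 that fell. Of 12 Notch pathway genes, the ligand gene Jag2 alone passed the test (0.88 ± 0.11). None of 24 cell cycle genes passed it, by limma over all genes or adjusted over the list alone. The proliferation marker gene Mki67 was at -0.19 ± 0.14 (adjusted p = 0.440), Mcm6 at -0.17 ± 0.22 and Birc5 at -0.10 ± 0.14. An unadjusted p under 0.05 was reached by 4 of the 24.

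The stem cell list passed camera's test of lists (camera adjusted p = 0.0122, and adjusted p = 0.303 with an estimated correlation). The Wnt list (median 0.17, mice 1 and 2: 0.17 and 0.17, camera adjusted p = 0.308), the Notch list (median -0.03, mice 1 and 2: 0.01 and -0.08, camera adjusted p = 0.658) and the cell cycle list (median -0.04, mice 1 and 2: -0.15 and 0.05, camera adjusted p = 0.509) did not. With limma's p adjusted over the list alone, 7 Wnt targets rose and 2 fell, and 1 Notch gene rose. Smoc2, Ephb3, Slc12a2, Myc, Mmp7 and Jag2 lost their calls with median centring; Slc12a2 and Myc with the scanner's own ratios and the deposited matrix; Smoc2 and Slc12a2 with no dim-probe filter; Myc and Jag2 with the organoid in Cy3 alone; Slc12a2 with the organoid in Cy5 alone. Jag2 was at 1.89 and 1.86 with the scanner's own ratios and the deposited matrix. The Notch median was above 0 with no dim-probe filter, and the cell cycle median with the organoid in Cy5 alone. The cell cycle list's median with median centring was 0.31 against a median of 0.17 over all genes.

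**Figure D2:**
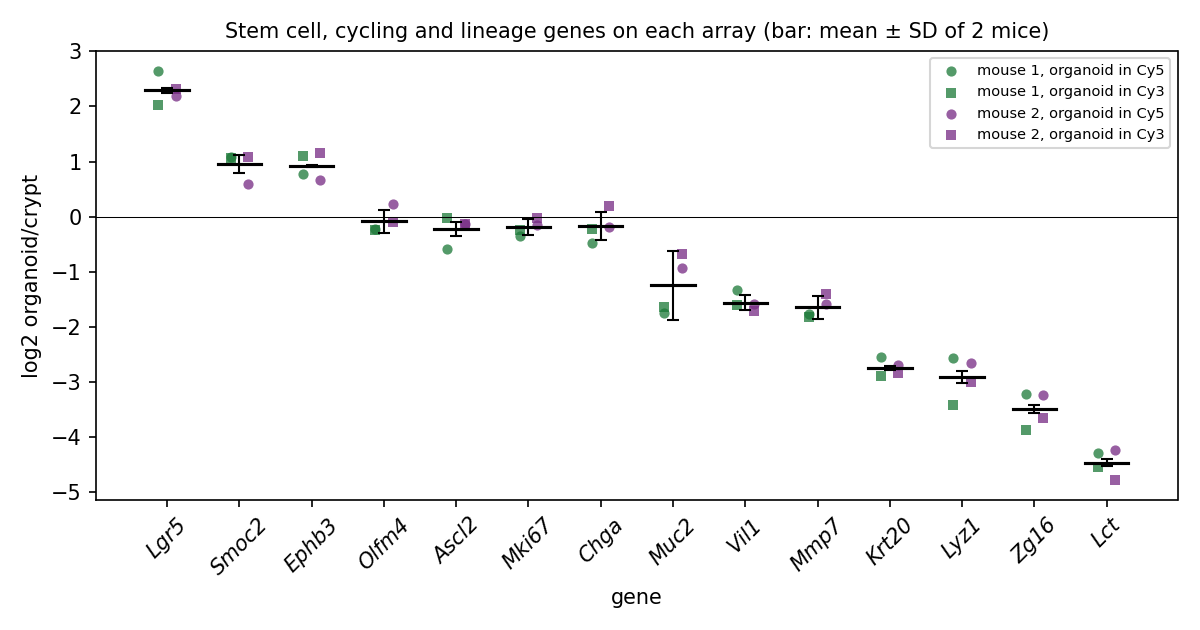
Log2 ratio of organoid over crypt (y axis) on each of the 4 arrays for stem cell, cycling and lineage genes (x axis), with circles for organoid in Cy5 and squares for organoid in Cy3. Black lines give the mean and SD of the 2 mice, from 2.29 for Lgr5 to -4.47 for Lct.

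Genes of the differentiated absorptive cells fell. Of 26 enterocyte genes tested, 22 were lower in organoids, none was higher and 4 did not pass the test, with a median of -1.72 (mice 1 and 2: -1.74 and -1.61). Besides Lct and Cubn, the keratin gene Krt20 had -2.75 ± 0.03 (adjusted p = 0.00152), and Vil1, which encodes the microvillus protein villin, -1.56 ± 0.13 (adjusted p = 0.00483; chromosome 1, 74481962 to 74482021). Of 17 genes of Paneth cells, the granular cells beside the stem cells, 14 fell and none rose, with a median of -1.67 (mice 1 and 2: -1.90 and -1.50). The lysozyme gene Lyz1 was 7.55-fold lower (-2.92 ± 0.11, adjusted p = 0.00152; chromosome 10, 116725254 to 116725313), and the antimicrobial ribonuclease gene Ang4 had -2.54 ± 1.05. The defensin gene Defa23 had -2.64 ± 0.01, but defensin genes are near-identical copies, so which of them each probe measured is uncertain. Many of the 17 Paneth cell genes are defensin genes, so the 14 that fell are not independent. The list's estimated correlation was 0.38, against the preset 0.01. Of 11 genes of the mucus-secreting goblet cells, 7 fell and none rose (median -1.25, mice 1 and 2: -1.64 and -0.80). Zg16 had -3.50 ± 0.07, Clca1 -3.07 ± 0.31, Ccl6 -2.25 ± 0.66 and the mucin gene Muc2 -1.25 ± 0.63 (adjusted p = 0.0336). Of 22 genes of hormone-secreting cells, the secretin gene Sct alone passed the test (-1.60 ± 0.00), and the granule protein gene Chga was at -0.17 ± 0.25 (adjusted p = 0.526). No gene of 12 of the chemosensory tuft cells passed limma's test or the adjustment over the list alone, with Alox5ap at 0.20 ± 0.54. Of the tuft cell genes, 0 had an unadjusted p under 0.05.

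The enterocyte list (camera adjusted p = 1.20e-22, and adjusted p = 0.302 with an estimated correlation), the Paneth cell list (camera adjusted p = 2.33e-13, and adjusted p = 0.303 with an estimated correlation) and the goblet cell list (camera adjusted p = 8.48e-09, and adjusted p = 0.303 with an estimated correlation) passed camera's test. The tuft cell list did not (median 0.12, mice 1 and 2: -0.08 and 0.30, camera adjusted p = 0.854), nor did the enteroendocrine list (camera adjusted p = 0.767). The enteroendocrine list had a median of 0.02 (mice 1 and 2: -0.17 and 0.18), which was below 0 without background subtraction, with the deposited matrix and with the organoid in Cy5 alone, a mean of -0.04 and a downward direction by camera. With p adjusted over the list alone, 25 enterocyte, 15 Paneth cell, 9 goblet cell and 1 enteroendocrine gene fell. Muc2, Vil1 and Sct lost their calls with median centring; Muc2, Ang4 and Ccl6 with no dim-probe filter; Muc2 with the scanner's own ratios, the deposited matrix and the organoid in Cy3 alone. Muc2 was at -0.80 in mouse 2 alone.

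Signalling readouts moved in both directions. Of 10 targets of BMP, the pathway that Noggin blocks, 6 fell and none rose (median -1.06, mice 1 and 2: -0.90 and -1.24), with Id1 at -3.06 ± 0.11 (adjusted p = 0.00143), Id3 at -2.67 ± 0.37 and Bambi at -1.38 ± 0.17. Of 12 targets of the MAP kinase pathway, which EGF activates, 6 rose and none fell (median 0.60, mice 1 and 2: 0.65 and 0.72). Phlda1 rose by 2.23 ± 0.22, the EGF receptor ligand gene Areg by 2.11 ± 0.23 and the phosphatase gene Dusp4 by 1.74 ± 0.07. Of 13 genes of regenerating or fetal epithelium, 6 rose (median 0.79, mice 1 and 2: 0.75 and 1.15), among them the annexin gene Anxa3 (2.70 ± 0.16) and the clusterin gene Clu (2.25 ± 0.17). The cytokine gene Il33 was the 1 that fell, at -2.54 ± 0.31, and it was well above background on 2 of the 4 organoid channels. Of 16 p53 target genes, 7 rose, among them Phlda3 (1.84 ± 0.27), the cell death gene Bbc3 (1.5 ± 0.57) and Gdf15 (1.16 ± 0.42). The death receptor gene Fas fell (-0.68 ± 0.09), and the median was 0.53 (mice 1 and 2: 0.50 and 0.59).

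Camera called the BMP list (camera adjusted p = 2.11e-05, and adjusted p = 0.313 with an estimated correlation), the MAP kinase list (camera adjusted p = 4.18e-05, and adjusted p = 0.303 with an estimated correlation), the regenerative list (camera adjusted p = 3.00e-06, and adjusted p = 0.303 with an estimated correlation) and the p53 list (camera adjusted p = 0.00352, and adjusted p = 0.303 with an estimated correlation). Adjusted over the list alone, 7 BMP targets fell. By the same adjustment 7 MAP kinase targets rose and 1 fell, 11 regenerative genes rose and 1 fell, and 9 p53 targets rose and 1 fell. Bambi, Gdf15 and Fas lost their calls with median centring; Bbc3, Gdf15 and Fas with no dim-probe filter; Fas with the scanner's own ratios, the deposited matrix, the mean over probes and the organoid in Cy3 alone. The BMP median was at -1.66 and -1.70, the regenerative median 2.07 and 2.06 and Il33 -4.69 and -4.70 with the scanner's own ratios and the deposited matrix.

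Genes of sterol and fatty acid synthesis rose. Of 22 genes of cholesterol synthesis and uptake, 19 rose and none fell (median 1.24, mice 1 and 2: 1.38 and 1.11), with Mvd at 2.04 ± 0.34 and Msmo1 at 1.93 ± 0.29. Of 12 lipogenesis genes, 7 rose and none fell (median 0.80, mice 1 and 2: 1.00 and 0.73), with Scd2 at 4.76 ± 0.22, Scd1 at 2.88 ± 0.27 and the malic enzyme gene Me1 at 1.24 ± 0.03. Of 22 genes of glycolysis and the hypoxia response, 15 rose and none fell (median 1.54, mice 1 and 2: 1.78 and 1.14), with Bnip3, Ankrd37 and Egln3 the highest. Of 24 genes of oxidative phosphorylation, 10 fell and none rose (median -0.54, mice 1 and 2: -0.54 and -0.55), among them the cytochrome c gene Cycs (-1.23 ± 0.42), Uqcrb (-0.80 ± 0.13) and Sdhb (-0.79 ± 0.24). Of 19 genes of fatty acid oxidation, 7 fell (median -0.50, mice 1 and 2: -0.51 and -0.50), including Cpt1a (-1.72 ± 0.09), which encodes the enzyme of mitochondrial fatty acid entry. The acyl-CoA thioesterase gene Acot1 was the 1 of them that rose (1.59 ± 0.37). Of 4 bile acid genes, the transporter subunit genes Slc51b (-2.52 ± 0.62) and Slc51a (-2.06 ± 0.17) fell (median -1.06, mice 1 and 2: -1.08 and -1.22).

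Camera called the cholesterol list (camera adjusted p = 9.18e-15, and adjusted p = 0.319 with an estimated correlation), the lipogenesis list (camera adjusted p = 5.97e-07, and adjusted p = 0.319 with an estimated correlation) and the glycolysis and hypoxia list (camera adjusted p = 2.72e-13, and adjusted p = 0.375 with an estimated correlation). It also called the oxidative phosphorylation list (camera adjusted p = 6.79e-10, and adjusted p = 0.303 with an estimated correlation), the fatty acid oxidation list (camera adjusted p = 6.27e-06, and adjusted p = 0.303 with an estimated correlation) and the bile acid list (camera adjusted p = 0.0195, and adjusted p = 0.328 with an estimated correlation). When adjusted over the list alone, 20 cholesterol, 10 lipogenesis and 19 glycolysis and hypoxia genes rose. By the same adjustment 20 oxidative phosphorylation, 13 fatty acid oxidation and 2 bile acid genes fell, and 1 fatty acid oxidation gene rose. Me1, Cycs, Uqcrb, Sdhb, Cpt1a, Acot1 and Slc51a lost their calls with median centring; Cycs, Uqcrb, Sdhb, Acot1 and Slc51b with no dim-probe filter; Uqcrb and Sdhb with the scanner's own ratios and the deposited matrix; Sdhb with the organoid in Cy3 alone. The oxidative phosphorylation median was at -0.30 and -0.56 with median centring and with loess, both relative to all genes; the fatty acid oxidation median -0.77 with the organoid in Cy5 alone; the bile acid median -0.005 with no dim-probe filter. The bile acid list lost its call without the dim-probe filter and with the organoid in Cy3 alone.

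Interferon-stimulated and MHC class II genes fell. Of 22 interferon-stimulated genes, 17 fell and none rose (median -1.49, mice 1 and 2: -1.39 and -1.67), with the immunoproteasome gene Psmb8 at -3.31 ± 0.15, the GTPase gene Igtp at -3.31 ± 0.06 and the antiviral gene Oasl2 at -3.08 ± 0.46. All 7 MHC class II genes tested fell (median -2.57, mice 1 and 2: -2.64 and -2.50), among them H2-DMb1 (-3.12 ± 0.09), Cd74 (-2.92 ± 0.29) and H2-Eb1 (-2.79 ± 0.05). Of 13 genes that respond to microbes, 4 fell: Reg3b, Reg3g (-2.83 ± 0.20), the antibody transporter gene Pigr (-1.30 ± 0.04) and Duoxa2 (-0.65 ± 0.16). The chemokine gene Ccl20 rose (0.84 ± 0.38). Markers of white blood cells were measured beside them. Of 16 T cell genes, 9 fell and none rose (median -0.70, mice 1 and 2: -0.82 and -0.61), with Ccl5 at -3.51 ± 0.14 and the granzyme genes Gzma at -2.80 ± 0.15 and Gzmb at -1.90 ± 0.20. Gzma was well above background on 1 and Gzmb on 3 of the 4 organoid channels. Of 8 B and plasma cell genes, the immunoglobulin gene Igh-2 (-2.0 ± 0.01) and Jchain fell. Jchain was not well above background in any organoid channel and was at least 1.74-fold lower there (adjusted p = 0.0223). Of 9 myeloid genes, Lyz2 (-2.32 ± 0.18) and the cathepsin gene Ctss (-1.25 ± 0.37) fell. Lyz2 and the Paneth cell gene Lyz1 are near-identical copies, so both values are uncertain. The myeloid list's mean was -0.55 against a median of -0.22, so few members, Lyz2 among them, carry its fall.

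Camera called the interferon list (camera adjusted p = 6.87e-17, and adjusted p = 0.303 with an estimated correlation), the MHC class II list (camera adjusted p = 1.11e-10, and adjusted p = 0.303 with an estimated correlation), the T cell list (camera adjusted p = 1.08e-08, and adjusted p = 0.375 with an estimated correlation) and the myeloid list (camera adjusted p = 0.00617, and adjusted p = 0.303 with an estimated correlation; median -0.22, mice 1 and 2: -0.15 and -0.34). The microbe-responsive list (median -0.05, mice 1 and 2: -0.13 and -0.11, camera adjusted p = 0.0826) and the B and plasma cell list (median -0.15, mice 1 and 2: -0.17 and -0.14, camera adjusted p = 0.108) did not pass. With median centring both of these lists passed camera's test with the preset correlation, and the microbe-responsive median was 0.12, against 0.17 over all genes. In the main processing, camera with an estimated correlation gave the microbe-responsive list adjusted p = 0.329 and the B and plasma cell list 0.640. Adjusted over the list alone, 20 interferon, 7 MHC class II, 11 T cell, 2 myeloid and 2 B and plasma cell genes fell, and 4 microbe-responsive genes fell and 1 rose. Pigr, Duoxa2, Ccl20, Jchain and Ctss lost their calls with median centring; Pigr, Duoxa2, Ccl20, Gzmb and Jchain with the organoid in Cy3 alone; Duoxa2, Ccl20, Jchain and Ctss with no dim-probe filter; Duoxa2 with an intensity trend and robust prior. The interferon median was at -2.74 and -2.76, the T cell median -2.05 and -2.05, the myeloid median -0.33 and -0.35, Duoxa2 -1.04 and -1.05, Ccl20 1.55 and 1.55, Gzma -5.75 and -5.72 and Gzmb -3.80 and -3.82 with the scanner's own ratios and the deposited matrix; the T cell median -0.27 with only probes well above background in all channels; the T cell median -0.40 and Ccl20 0.51 with the organoid in Cy3 alone; the myeloid median -0.34 in mouse 2 alone; Lyz2 -1.45 with the mean over probes. The interferon median was -1.46 with the 4 members not well above background in a tissue set at their bounds.

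Markers of other tissues were also examined. Tested were 4 of 20 mesenchyme, 3 of 12 glia and neuron and 7 of 15 endothelial genes on the array. Of muscle and red blood cell genes on the array, 4 of 9 and 4 of 7 were tested. The others did not pass the filters, so list medians near 0 do not show that such tissue was unchanged. No gene of 4 of mesenchyme (median 0.10, mice 1 and 2: 0.01 and 0.13; Vim 0.21 ± 0.34, Col1a2 -0.00484 ± 0.05), 3 of glia and neurons (median 0.12, mice 1 and 2: -0.04 and 0.28; S100b 0.40 ± 0.65, Sox10 0.03 ± 0.07) or 4 of red blood cells (median 0.10, mice 1 and 2: -0.01 and 0.21; Hemgn 0.40 ± 0.22, Hbb-bt 0.11 ± 0.12) passed limma's test. Of 7 endothelial genes, Lyve1 alone passed and rose (1.03 ± 0.40; list median 0.05, mice 1 and 2: -0.08 and 0.09). Of 4 muscle genes, Mylk (-2.15 ± 0.23), a myosin light chain kinase gene, and the smooth muscle actin gene Acta2 (-0.66 ± 0.01) fell. Camera called the muscle list (median -0.58, mice 1 and 2: -0.56 and -0.60; camera adjusted p = 0.00617, and adjusted p = 0.303 with an estimated correlation), a call that ended without the dim-probe filter. It did not call the mesenchyme (adjusted p = 0.647), endothelium (0.915), glia and neuron (0.586) or red blood cell (0.514) lists. Over these 5 lists the adjustment over the list alone gave 3 muscle genes lower and 1 endothelial gene higher. An unadjusted p under 0.05 was reached by 0 mesenchyme, 0 glia and neuron and 1 red blood cell gene. Lyve1, Mylk and Acta2 lost their calls with median centring; Lyve1 and Acta2 with no dim-probe filter and the organoid in Cy3 alone; Acta2 with the scanner's own ratios, the deposited matrix and the mean over probes. The muscle median was at -0.037 with no dim-probe filter; Lyve1 0.57 with the organoid in Cy3 alone; Acta2 -0.31 with the mean over probes.

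Genes of detoxification and metal handling included the largest rises. Of 14 genes under the stress regulators NRF2 and AHR, 6 rose, Cbr3 and the glutathione transferase genes Gsta3, Gstm1 (2.92 ± 0.00), Gsta1, Gsta2 and Gsta4. No other member rose past the test: Nqo1, Hmox1, Gclc, Gclm, Txnrd1 and Tiparp did not pass it. Gsta1 and Gsta2 are near-identical copies and their values are uncertain. Srxn1 (-1.01 ± 0.48) and Cyp1a1 fell, the latter not well above background in any organoid channel and at least 1.51-fold lower there (adjusted p = 0.0156), and the list's median was 0.71 (mice 1 and 2: 1.27 and 0.31). Of 14 metal-handling genes, 5 rose and 3 fell. Mt2 (3.92 ± 0.10), Cybrd1 (3.08 ± 0.31), Mt1 (2.80 ± 0.20), Ftl1 (0.73 ± 0.01) and Mt4 (0.71 ± 0.02) rose, and the zinc transporter gene Slc39a4 (-1.77 ± 0.10), Fth1 (-1.04 ± 0.00) and the transferrin receptor gene Tfrc (-0.68 ± 0.21) fell. Of 18 genes of the unfolded protein response, Atf5 (2.53 ± 0.16), the asparagine synthetase gene Asns (1.90 ± 0.22) and Sesn2 (0.90 ± 0.02) rose, and Sdf2l1 (-1.19 ± 0.50), Creld2 (-1.07 ± 0.43) and Hsp90b1 (-0.66 ± 0.01) fell. Of 18 immediate early genes, Nr4a1 (1.75 ± 0.79), Ier3 (0.80 ± 0.08) and Jun (0.66 ± 0.07) rose, and Fos (-2.54 ± 0.83) and Zfp36 (-0.96 ± 0.38) fell.

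Camera called the NRF2 and AHR list (camera adjusted p = 5.03e-04, and adjusted p = 0.303 with an estimated correlation) but not the metal, unfolded protein or immediate early lists (adjusted p = 0.754, 0.308 and 0.976). The metal list had a median of -0.13 (mice 1 and 2: 0.27 and -0.31), which turned to 0.21 with the mean over probes, a mean of 0.46 and an upward direction by camera. The unfolded protein list had a median of -0.29 (mice 1 and 2: -0.06 and -0.48), a mean of 0.00402 and a downward direction by camera. The immediate early list had a median of 0.01 (mice 1 and 2: 0.23 and -0.17), which was below 0 without background subtraction, with the mean over probes and with the organoid in Cy3 alone, a mean of -0.10 and an upward direction by camera. Adjusted over the list alone, 8 NRF2 and AHR genes rose and 3 fell, 5 metal genes rose and 4 fell, 3 unfolded protein genes rose and 6 fell, and 6 immediate early genes rose and 3 fell. Cyp1a1, Srxn1, Ftl1, Mt4, Slc39a4, Fth1, Tfrc, Sesn2, Sdf2l1, Creld2, Hsp90b1, Ier3, Jun, Fos and Zfp36 lost their calls with median centring; Srxn1, Ftl1, Mt4, Tfrc, Sdf2l1, Creld2, Hsp90b1, Nr4a1, Ier3, Jun, Fos and Zfp36 with no dim-probe filter; Cyp1a1, Srxn1, Mt4, Tfrc, Sdf2l1, Creld2, Ier3, Jun and Zfp36 with the organoid in Cy3 alone; Srxn1, Ftl1, Tfrc, Creld2, Hsp90b1 and Jun with the scanner's own ratios and the deposited matrix; Srxn1, Hsp90b1 and Zfp36 with the mean over probes; Ftl1 and Hsp90b1 with the organoid in Cy5 alone; Cyp1a1 with no background subtraction. The NRF2 and AHR median was at 0.45 with no dim-probe filter; Mt4 1.33 and 1.3 with the scanner's own ratios and the deposited matrix; Mt4 0.39 with the organoid in Cy3 alone; Fth1 -0.70 and -1.06 and Hsp90b1 -0.42 and -0.68 with median centring and with loess, both relative to all genes; Fth1 -0.66 with the organoid in Cy5 alone.

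**Figure D3:**
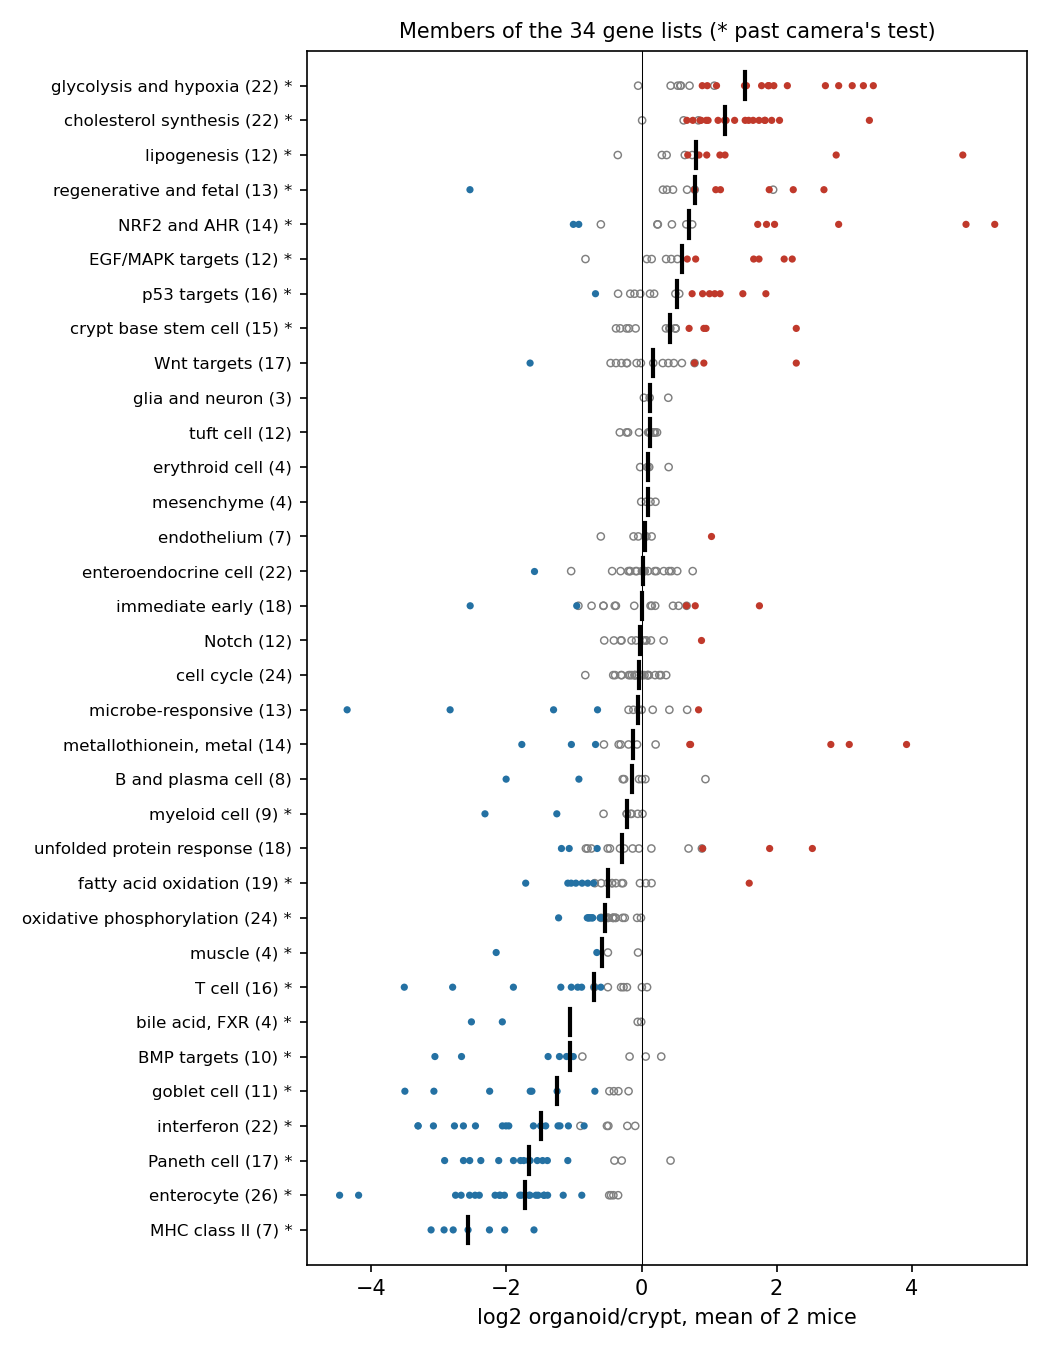
Log2 ratio of organoid over crypt (x axis, mean of 2 mice) of each tested member of the 34 gene lists (y axis, number tested in brackets). Filled points passed limma's test (red higher, blue lower), open points did not, black bars are list medians, and an asterisk marks the 20 lists that passed camera's test with the preset correlation (0 with an estimated correlation, 0 with fry), from MHC class II at -2.57 to glycolysis and hypoxia at 1.54.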

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

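Of 170 genes (named or taken by the naming rule), list medians and array measures, 10 had 1 array far from the other 3 by Dixon's gap test. Chance sets apart about 1 in 20 such groups, and the 4 arrays are 2 technical repeats from each of 2 mice. In mouse 2, Smoc2 was at 0.59 against 1.06 to 1.08 on the other 3 arrays and Vim at 0.90 against -0.07 to 0.00 on the other 3, both with the organoid in Cy5. With the organoid in Cy3 of the same mouse, Reg3b was at -4.74 against -4.28 to -4.19 on the other 3 and the Notch list's median at -0.17 against -0.01 to 0.01 on the other 3. In mouse 1 with the organoid in Cy3, Id3 was at -1.93 against -2.97 to -2.88 on the other 3 and Bambi at -0.95 against -1.58 to -1.49 on the other 3. On the same array Duoxa2 was at -0.30 against -0.79 to -0.74 on the other 3 and Gsta1, a near-identical copy of Gsta2 with an uncertain value, at 1.47 against 2.08 to 2.19 on the other 3. In mouse 1 with the organoid in Cy5, the enterocyte list's median was -1.84 against -1.65 to -1.62 on the other 3 and the microbe-responsive list's median -0.25 against -0.05 to -0.02 on the other 3.

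For the 3 patterns that follow, the tests of dye bias, of the stem cell share, of the second Lgr5 probe and of the hypoxia genes were chosen after the results were seen, and so was the list of white blood cell transcripts. The first pattern is the fall of interferon and MHC class II genes. The interferon list's median was -1.20 in the weaker of the 2 dye orientations. Dye bias already cancels in a mouse's mean over both orientations, so this value adds little against dye bias as a cause. Loss of white blood cell RNA as the whole cause of the interferon list's fall cannot be told apart from a fall within the epithelium. Of 16 transcripts shared by white blood cells, the 5 bright enough in crypts to fall as far had a median of 0.0141 (95% bootstrap interval -0.68 to 1.49, also their range), which met the bound set beforehand against this cause, but Lcp1 among them rose (1.49 ± 0.21), so organoid cells may make such transcripts and that bound was wrong. All 16 had a median of -0.33, but in the main processing the others were too dim in crypts to fall as far. Among them Cd52 and Srgn were not well above background in any organoid channel and were at least 1.62-fold and 2.08-fold lower there. Both passed the test (limma adjusted p = 0.0200 and 0.00875). These calls ended with median centring and with the organoid in Cy3 alone. With the scanner's own ratios Cd52 was at -3.50 and Srgn at -4.61, against an interferon median of -2.74. With the deposited matrix they were at -3.51 and -4.63, against -2.76. Both thus fell further than the interferon median there, but from organoid signals not well above background. They are the 2 of the 16 that passed the test as lower, and 1 passed as higher. The rest of the 16 are not given with these ratios, so the 2 do not stand for all of them. Lost white blood cells and a response of the epithelium to culture therefore both stay open, for the MHC class II genes too.

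The second pattern is the rise of Lgr5 by 2.29 ± 0.05 with smaller values of other stem cell genes. The 14 other stem cell genes had a median of 0.42, an upper quartile of 0.50 and a highest value of 0.95. This argues against a larger share of stem cells as the whole cause only if their markers would all rise alike, which was not tested. These smaller values are also part of the pattern itself, so they are no separate test of that cause. Cross-hybridisation of the Lgr5 probe cannot be told apart from a change of Lgr5 RNA, since the second Lgr5 probe was well above background in 0 of the 4 organoid channels. A response of Lgr5 itself to the culture medium stays open and was not tested.

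The third pattern is the rise of glycolysis and hypoxia genes. The loess normalization as its whole cause is argued against, since with median centring in its place the list's median was 1.88, against 0.17 over all genes. The list's median was 1.47 in the weaker dye orientation, which again adds little, since dye bias cancels in a mouse's mean. A hypoxia response was consistent with the median of 1.89 of the 11 members that are not glycolytic (2.61 in mouse 1 and 1.84 in mouse 2), against 0.97 for the 11 glycolytic ones. This is a hypothesis, found and tested on the same data, and oxygen was not measured.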

How the results depend on the processing

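The random block without a dye term was added after seeing the data; the other alternatives were planned. The 1697 genes past the test became 224 (130 higher, 94 lower) with median centring, of which 223 also passed in the main processing; it left the tested genes' median at 0.42 in mouse 1 and -0.02 in mouse 2. They became 677 (293 higher, 384 lower) without the dim-probe filter, which tests 28562 genes, and 908 (432 higher, 476 lower) with the organoid in Cy3 alone, which leaves 1 array per mouse. The 4 arrays as separate samples with a dye effect gave 3709 (1952 higher, 1757 lower), and the mouse as a random block 3080 (1590 higher, 1490 lower); both gain degrees of freedom from technical repeats. The other 10 alternatives gave 1436 to 2190. Genes at least 2-fold higher or lower in both mice (251 and 358) were 513 and 617 with the scanner's own ratios, 497 and 633 with the deposited matrix, and 364 and 194 with median centring; the cause was not tested. Without either mouse, which leaves values and no test, they were 379 to 484 higher and 426 to 733 lower. The 20 lists that camera called were 18 to 22 under the other processings, and 0 with an estimated correlation and 0 with fry. The microbe-responsive median turned from -0.05 to 0.12 with median centring, where the list gained a camera call, but was -0.07 and -0.05 relative to all genes. Of 116 genes past the test that are named or taken by the naming rule, 70 kept their call in each processing but median centring that tested them, and 50 lost it with median centring. With median centring the medians of the cell cycle, immediate early, endothelium, mesenchyme, glia and red blood cell lists, none of them called, changed sign relative to all genes, and so did the endothelium median without background subtraction. Channel correlations kept their order between tissues and mice. A mouse random block with a dye effect gave no estimate from 4 arrays, and a slide block was not run, since there was 1 slide. Signal over background limits what dim genes can show.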

Other observations

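Gene families that share the first letters of their symbols, tested after the results were seen, gave further groups (209 families with at least 8 genes tested, camera with preset correlation, Benjamini-Hochberg adjustment). The Rpl and Rps families hold the genes of cytosolic ribosomal proteins, and the Rps set also Rps19bp1, which is not one. Of 46 Rpl genes 15 rose, none fell and the others did not pass the test, with a median of 0.53 (0.45 in mouse 1, 0.57 in mouse 2), and of 32 Rps genes 12 rose and none fell, with a median of 0.57 (0.46 in mouse 1, 0.61 in mouse 2). Rpl9 rose by 0.94 ± 0.12, Rpl32 by 0.86 ± 0.02 and Rps14 by 0.91 ± 0.01. The camera adjusted p of the Rpl and Rps families was 1.39e-10 and 1.59e-09, and adjusted p = 0.9995 for each with an estimated correlation. Relative to all genes, the Rpl median ranged from 0.35 to 0.83 and the Rps median from 0.37 to 0.89 under 4 other processings. Rps6k kinase genes were taken out of the Rps group after a first result was seen. Rpl9, Rpl32 and Rps14 lost their calls with the scanner's own ratios, the deposited matrix, median centring and the organoid in Cy3 alone; Rpl9 with the mean over probes. Rpl9 was at 0.33 with the mean over probes; Rpl32 0.55 and Rps14 0.37 with the organoid in Cy3 alone; Rps14 1.44 with the organoid in Cy5 alone. Many processed copies of these genes exist, so single members are uncertain.

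Other families passed camera's test with the preset correlation. Of 13 carboxylesterase genes 3 rose and none fell (median 0.58, adjusted p = 0.00243, and adjusted p = 0.9995 with an estimated correlation), with Ces1d at 1.62 ± 0.07, Ces2a at 1.56 ± 0.18 and Ces1c at 1.52 ± 0.50. Of 10 annexin genes 4 rose and none fell (median 0.51, adjusted p = 0.00107, and 0.9995 with an estimated correlation), including Anxa10 (2.32 ± 0.55), Anxa1 (1.17 ± 0.11) and Anxa13 (0.81 ± 0.07) besides Anxa3, which is also in the regenerative list. Anxa10 and Anxa1 were well above background on 1 of the 4 crypt channels. Anxa10, Anxa1 and Anxa13 lost their calls with the organoid in Cy3 alone; Anxa1 and Anxa13 with median centring; Ces1c and Anxa10 with no dim-probe filter; Anxa13 with the scanner's own ratios and the deposited matrix. Anxa10 was at 5.35 and 5.32 and Anxa1 3.50 and 3.47 with the scanner's own ratios and the deposited matrix. Of 259 genes of solute carriers, 51 fell and 15 rose (median -0.07, adjusted p = 0.00661, and 0.9995 with an estimated correlation). Of 21 genes of the H2 complex, 16 fell and none rose (median -1.44, adjusted p = 4.95e-13, and 0.9995 with an estimated correlation). They include the MHC class II genes whose symbols start with H2, but not Cd74 or Ciita of the MHC class II list. In all, 18 families passed, and by camera with an estimated correlation none did (adjusted p = 0.9995 or more for each, 3 with an unadjusted p under 0.05). That test, with 2 residual degrees of freedom, has little power, so its result does not show that correlation accounts for a shift. The genes named here were chosen after their values were seen.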
